A study of Drosophila melanogaster with 4 samples.

How the data were processed

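RNA of adult midguts was extracted and sequenced as stranded mRNA libraries, per the labels' protocols, from 2 ADARcd and 2 CG6967-ADARcd samples. Per the submitters' processing notes, the tools were CASAVA 1.8, fastp 0.19.5, STAR 2.6.1c and Picard 2.18.20 with the dm6 genome. Their roles are not given in the sources used here, nor is the variant caller. Per the file headers, the columns follow the layout of the JACUSA caller, with 2 libraries in condition 1 and 1 in condition 2.

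The deposited base-count tables hold, per the file headers, 4 read counts per library and position, and a score from the authors' test of the difference in base composition between conditions. The deposited target lists hold gene identifiers, symbols and row numbers of sites, with no position, level or count. The base order was checked on annotated start codons: 1554 of 1557 listed positions (99.8%) read ATG on the given strand. The condition 1 counts were equal in both tables at all 984871 shared positions. Positions in the first table alone (271530) and in the second alone (292123) were without a condition 1 mismatch in 98.9% and 98.6% of cases.

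No column name gives a genotype or a sample, so the columns were treated as libraries of the authors' comparison and not as samples. The tables are recorded with the ADARcd samples. Each target list was found again from its own table and with the condition 2 library higher, which is an inference from the values. If the conditions were the other way round, every direction would turn. In the first table the odds ratio of A-to-G against T-to-C would then be 1.58 in place of 0.635 (two-sided Fisher's exact test p = 1.52e-07) and the A-to-G share 10.66% in place of 8.45%. In the second they would be 0.909 in place of 1.10 (Fisher's exact p = 0.208) and 9.87% in place of 10.8%. The listed positions would be lower in the fusion. The score bound of 1.56 was set from the data. It is the lowest score, rounded down, of listed genes in their own table at A-to-G positions higher in condition 2. All listed genes in the annotation thus reached it there by construction, and 54.4% and 35.9% did in the other table. That contrast leans towards the own table for the same reason. The filter behind the lists is not given in the sources used here. After several settings were tried on the files, positions were recovered with that score, at least 10 reads per library, at most 1% other bases, condition 2 above condition 1, and at most 20% A-to-G in condition 1. This gave 216 and 464 positions, of which 138 and 432 lay in listed genes, and only approximates the authors' filter. The A-to-G level is G over A plus G.

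Genes and regions came from the Ensembl annotation of the same assembly, with 17873 genes. The design written before the data were examined named a count model for the comparison of levels. Because a cell holds 4 joined counts, a quasi-binomial test was used in its place, with the Pearson dispersion moderated by limma 3.58.1 in R 4.3.3 and held at 1 or more. It took A positions in both tables with at least 20 reads in each library. They needed at least 5 G reads in all and at most 1% other bases. The minimum of 5 G reads was not in that design. Minimums of 1, 2, 3, 5 and 10 were run on the data and on 10 sets of simulated libraries with spread taken from the condition 1 libraries. With no difference, the false calls averaged 14.9, 0, 18.4, 0.2 and 0.1, and the minimum of 2 recovered 0% of changed positions. With changed positions at an odds ratio of 16, 23.7 of 218.6 calls were false at the minimum of 5, a share above the nominal 0.05.

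Other tests were Fisher's exact tests and Clopper-Pearson 95% intervals (SciPy 1.17.1, Python 3.11.15). Adjustment was by Benjamini-Hochberg at 0.05. The background for overlap and gene lists was genes with an A position covered by 20 reads in all libraries. A table lists only mismatched positions, so this background leaves out covered genes without one. The gene lists were fixed beforehand and matched by symbol. Of 594 entries, 24 were matched through an older name held by 1 gene, and 22 were not matched. The rule for named genes took the first 25 genes in both lists, by number of shared positions and then mean level. It added the 5 genes of highest level in each list alone, CG6967 and Adar, every member of a gene list in both target lists, and up to 3 per gene list in 1 of them. The position given for a gene is that of its highest level. Not every gene the rule names is reported here. The controls were drawn from a common level 100 times for the shared-library comparison. Stricter levels, coverage minimums, backgrounds, left-out libraries and the other test were run as alternatives, and leaving out the X chromosome was added after the data were seen. Sequence context was not analysed here, as it needs the genome sequence.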

Results

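The RNA targets of CG6967, a protein of the RNA helicase family that the gene annotation names Mov10, were surveyed in the adult midgut of Drosophila melanogaster with TRIBE. In TRIBE an RNA-binding protein is fused to the catalytic domain of the RNA-editing enzyme ADAR (ADARcd). Adenosines near the bound sites are then read as guanosines, so that targets carry A-to-G mismatches. Flies of 2 genotypes, aged 7 to 8 days, expressed either the editing domain alone (ADARcd, 2 samples) or the fusion (CG6967-ADARcd, 2 samples), under an esg driver system named in the genotype labels. The deposited files analysed were of 2 kinds. For each CG6967-ADARcd replicate there was a list of target genes, and each ADARcd replicate was recorded with a table of base counts at mismatched positions on the dm6 genome. Each table set 2 libraries of a condition 1, the same 2 in both tables, against 1 library of a condition 2.

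No column header names a genotype. The genes in the target list of CG6967-ADARcd replicate 1 were found again as genes with A-to-G positions higher in the condition 2 library of the first table for 121 of 128 genes, against 27 with a position lower there. In the second table, 316 of the 324 genes of the list of replicate 2 were found again, against 24. Condition 2 is read below as the fusion on this ground alone, and every direction given for the conditions rests on that reading. The score behind these counts was taken from listed genes at positions higher in condition 2, which leans the counts towards that direction. The first table held 1256401 positions and the second 1276994, of which 984871 were in both. Median reads per position were 163 and 171 in the condition 1 libraries and 160 in the condition 2 library of the first table, and 168 in that of the second. These tables hold only positions with a mismatch, so the reads do not give library depth.

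The first question was which transcripts the fusion marked in each replicate. The authors' deposited list of replicate 1 named 128 genes with 136 sites, and that of replicate 2 named 324 genes with 438 sites. CG10505 had the most sites in replicate 1 (6), and CG14200 the most in replicate 2 (6). The lists give no positions or levels, so positions were recovered from the tables in listed genes, 138 for replicate 1 and 432 for replicate 2. At these positions the median A-to-G level in condition 2 was 17.2% in the first table and 17.02% in the second, against medians of 4.72% and 1.71% over the 2 condition 1 libraries. The positions were kept for a higher level in condition 2 and a low one in condition 1. The gap between the medians therefore follows from the selection and is no evidence of editing. The median reads behind a condition 2 level were 70 and 60. The positions of replicate 2 lay mostly on the X chromosome, 296 of 432 (68.5%, 95% Clopper-Pearson interval 63.9 to 72.9%). In replicate 1 the X chromosome held 12 of 138 (8.70%, 4.57 to 14.7%), a difference past a two-sided Fisher's exact test (odds ratio 22.9, p = 1.81e-37). Away from the X chromosome the lists were close in length, with 126 and 136 positions. Intervals cover counting error only.

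The second question was whether the replicates marked the same transcripts. The lists shared 44 genes, 34.4% of the genes of replicate 1 and 13.6% of those of replicate 2. Among 5967 genes with a covered A position, 6.38 shared genes would be given by independent lists (odds ratio 11.7, one-sided Fisher's exact test p = 1.86e-26). Exact positions were shared 48 times. Both lists were made against the same 2 condition 1 libraries, which raises their overlap without any difference between conditions. With 4 libraries drawn from a common level at the same positions, a one-sided Fisher cut of 0.001 called a mean of 37.6 A-to-G positions in both tables over 100 draws (range 27 to 51). In the data the same cut called 37, and independent lists of the observed lengths would share 2.65. The draws held more calls in the first table than the data did, a mean of 182.3 against 110, so they do not match the data there. Why was not tested. Of the positions called in the first table, 33.6% were also called in the second in the data and a mean of 20.6% in the draws. Part of the excess over independent lists may come from the shared libraries.

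Several positions shared by both lists were free of G reads in condition 1 in the authors' deposited tables. CG10505 (FBgn0034612, 2R, 21285248 to 21290343) had 5 shared positions, the most of any gene, all at 0% in condition 1. Its further position, recovered for replicate 1 alone (21286307), was at 13.6% of 81 and 15.2% of 105 reads there. At the shared coding position 21286831 of CG10505 the A-to-G level was 0% of 76 and 73 reads in condition 1 and 15.7% of 83 reads (95% interval 8.61 to 25.3%) and 23.8% of 80 reads (15.0 to 34.6%) in condition 2. The neighbouring MFS16 (FBgn0034611, 2R, 21282298 to 21285679), on the opposite strand and overlapping CG10505 in span, had 3 shared positions. Of these, 21284750 and 21284938 were at 0% in condition 1, with 9.35% and 8.33%, and 5.66% and 7.25%, in condition 2. At 21283460 MFS16 was already at 19.2% and 4.84% in condition 1, against 22.9% and 21.4%. Whether the positions of these neighbouring genes are sequence variants carried together was not tested. The coding position 15116756 of stc (FBgn0001978, 2L) stood at 0% in both condition 1 libraries and at 19.6% and 24.5% in condition 2. PMCA (FBgn0259214, chromosome 4), a plasma membrane calcium pump, had 25.7% of 35 reads and 30.8% of 39 reads at the 5′ UTR position 358620, with none in condition 1. The coding position 22262921 of dve (FBgn0020307, 2R), a homeobox gene, had 28.6% and 23.1%, from 14 and 13 reads.

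At other shared positions at least 1 condition 1 library was near the level of condition 2. In the 3′ UTR of egl (FBgn0000562, 2R, position 23735262) the levels in the authors' deposited tables were 0% and 20.9% in condition 1 and 23.4% and 26.6% in condition 2. For Cyp309a1 (FBgn0031432, 2L, position 2562988, coding) they were 3.10% and 20.3% against 15.9% and 17.01%. CG8671 had 18.2% and 0% against 17.2% and 21.2%, and CG17493 had 16.5% and 5.88% against 21.2% and 21.4%. Other positions stood higher in condition 2 with G reads in both condition 1 libraries. The coding position 20339340 of spir, an actin nucleator, was the highest of the shared genes in the first table, with 50% in condition 2 of that table and 38.2% in the second, against 26.2% and 12.7%. The 3′ UTR position 7444940 lies in both kappaB-Ras and CG30503, whose annotated spans are equal, and cannot be given to either. Levels of 40.0% and 32.0% were read there against 4.76% and 19.2%. The rest of the 25 genes ranked first among those in both lists were Spred, Dap160, Dnz1, Rab3-GAP, Bacc, Fkbp14, CG2915, CG14749, tai, PGRP-SC1a, tweek, Lpin and CG10592. CG10592 was the lowest, at 0.102% of 1965 reads and 0.100% of 2001. At its other shared position, 5593111, condition 2 was at 0.0324% and 0.0316%, against 0.0350% and 0% in condition 1. Each deposited list holds 1 site for this gene, so its rank by shared positions is uncertain.

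**Figure D1:**
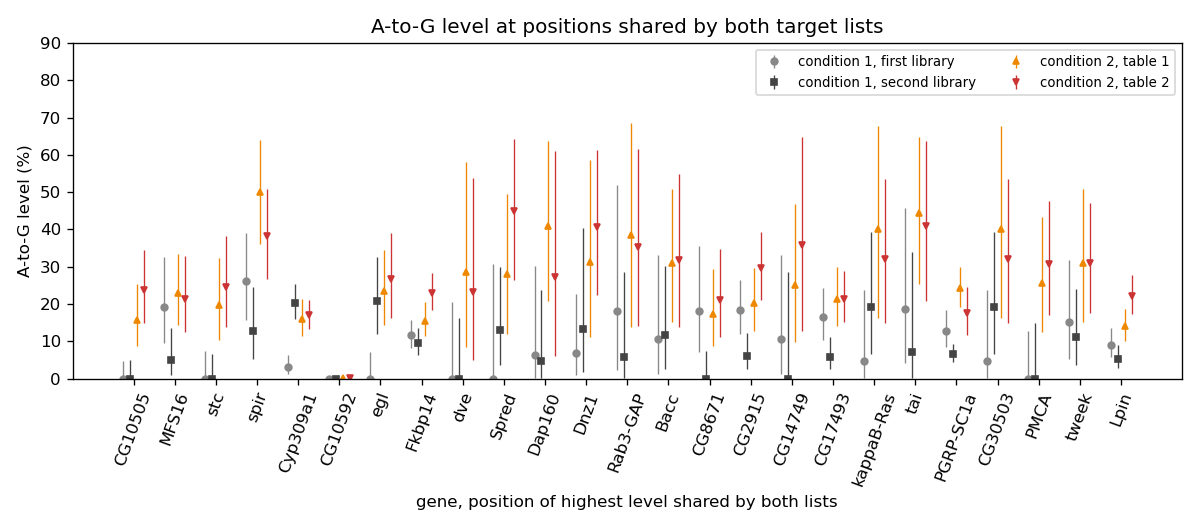
A-to-G level in percent (vertical axis) at the position of highest level in each of 25 genes named by both target lists (horizontal axis), for the 2 condition 1 libraries and the condition 2 library of each table. Points are levels and lines are 95% Clopper-Pearson intervals. CG10505, stc, dve and PMCA stood at 0% in both condition 1 libraries, while the condition 1 libraries of egl stood at 0% and 20.9%.

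Genes found in 1 list only included the highest levels, mostly from few reads. In replicate 2, beta3GalTII reached 58.3% of 12 reads (27.7 to 84.8%), CG9981 55.2% of 116, Sf3b1 54.5% of 11, CG10721 53.3% of 15 and RpIII128 52.6% of 19 in condition 2 of the second table. Sf3b1 was at 44.4% in condition 2 of the first table and at 27.3% and 9.09% in condition 1, and CG10721 at 31.2% and at 28.6% and 5%. RpIII128 was at 19.2% and at 4.55% and 12.5%. The same beta3GalTII position was at 50% in condition 2 of the first table and at 45.5% and 0% in condition 1. CG9981, on the X chromosome, was at 0% in condition 2 of the first table and at 0% and 14.7% in condition 1. In replicate 1 the leading genes were CG8771 at 50% of 12 reads, CG42321 at 45.2% of 31, CG5149 at 41.3% of 63, CG6613 at 39.3% of 28 and the non-coding CR45604 at 38.1% of 21. In condition 2 of the second table they were at 20%, 20.8%, 22.1%, 21.9% and 23.5%. Each had G reads in at least 1 condition 1 library, from 13.04% to 18.2% in the first. Adar itself (FBgn0026086, X, 1773725 to 1788065) was listed in replicate 1. The coding position 1781840 lies in both Adar and prage and cannot be given to either. It read 1.86% of 430 reads in condition 2 of the first table and 1.03% of 485 in the second, against 1.07% and 0%. Mov10, the annotated CG6967, was in neither list.

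Levels were next compared between conditions over all 4 libraries. No A-to-G position passed a quasi-binomial test with limma's moderated dispersion and Benjamini-Hochberg adjustment, 0 higher and 0 lower of 8374, with a lowest adjusted p of 0.945. At an unadjusted p under 0.05, 123 positions were higher and 194 lower in condition 2, together 3.79% of those tested. Only positions in both tables were tested. This keeps positions with a condition 1 mismatch and drops those mismatched in 1 condition 2 library alone, which tilts the tested set towards lower. The balance of higher and lower positions also depended on single libraries. It was 153 higher and 25 lower without the condition 2 library of the first table and 42 and 85 without that of the second. Without the first condition 1 library it was 130 and 126, and without the second 91 and 259. More positions differed when the second condition 1 library and condition 2 of the second table were set against the other pair, 276 higher and 189 lower. The remaining grouping gave 115 and 145, and neither gave a call by the limma-moderated test after adjustment. Fisher's exact test of each condition 2 library against the condition 1 reads, adjusted and past 0.05 in both tables, gave 38 higher and 95 lower positions. It compares libraries, not conditions, and took the same tilted set of positions. Without the minimum of 5 edited reads over the libraries, a minimum set after the files were seen, the limma-moderated test called 69 higher and 134 lower positions. That setting also called 245 and 139 positions when the 4 libraries were regrouped in the other 2 ways. On simulated libraries with no difference it made a mean of 14.9 false calls, against 0.2 with the minimum. With the minimum, the test recovered 16.7% of simulated positions changed by an odds ratio of 4 and 97.5% of those changed by 16. The simulated spread came from the condition 1 libraries alone, so these shares may not hold for the data. Position 21286831 of CG10505, at 0% in condition 1 and at 15.7% and 23.8% in condition 2, also gave no call. The lack of calls therefore does not exclude large changes.

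A-to-G mismatches were then set against the other kinds, which ADAR does not make and which give the background of errors and sequence variants. Among mismatches over 5%, A-to-G made up 13.02% and 13.01% in the condition 1 libraries (intervals 12.7 to 13.4% and 12.7 to 13.3%), and 13.1% in both condition 2 libraries (12.7 to 13.4% and 12.8 to 13.4%). Among positions higher in condition 2 and past the statistic of the lists, A-to-G ranked 4 of the 12 kinds in both tables. Its share was 8.45% (7.40 to 9.59%) in the first table and 10.8% (9.87 to 11.8%) in the second. The shares are of 2557 and 4303 counts, as a position was counted under each kind that rose. The score behind a position need not come from that kind. T-to-C led with 24.9% and 21.3%. The A-to-G positions higher in condition 2 were 216 and 464, against 1000 and 661 lower by the same statistic. The higher positions were also limited to low levels in condition 1, and the lower ones in the same way to low levels in condition 2. These counts alone do not settle the balance of directions. Adjusted Fisher's exact tests, on positions in both tables, called 116 higher and 210 lower in the first table. In the second they called 214 higher and 132 lower, so the excess of lower positions was not kept there. Set against positions lower in condition 2, A-to-G was less frequent than T-to-C in the first table (odds ratio 0.635, two-sided Fisher's exact test p = 1.52e-07). In the second table no difference from T-to-C passed the same test (odds ratio 1.10, Fisher's exact p = 0.208). With positions called by Fisher's exact test in each table, the difference in the first table was lost. The odds ratios were then 0.869 (Fisher's exact p = 0.389) and 1.11 (Fisher's exact p = 0.499).

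**Figure D2:**
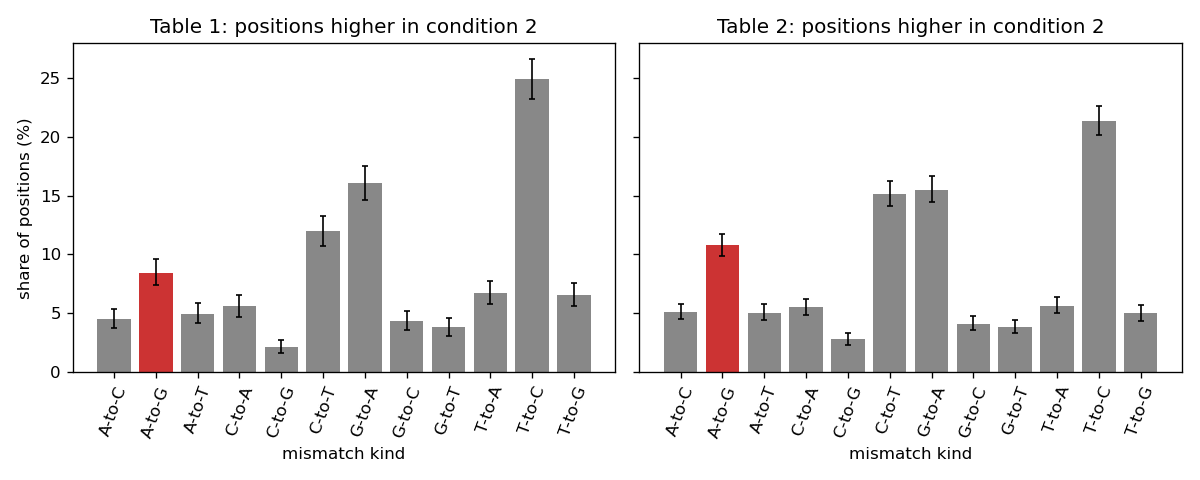
Share in percent (vertical axis) of each of the 12 mismatch kinds (horizontal axis) among positions higher in condition 2, for the first and the second table. Bars are shares, lines 95% Clopper-Pearson intervals and A-to-G is in red. A position counts under each kind that rose. A-to-G stood at 8.45% and 10.8%, below T-to-C at 24.9% and 21.3%.

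Of 20 gene lists fixed before the data were examined, none was enriched after Benjamini-Hochberg adjustment over lists and replicates. Among genes in both lists, translation factors came closest, with 2 members where 0.207 were given by chance (one-sided Fisher's exact test p = 0.0178, adjusted p = 0.377). Random gene sets matched for the number of covered positions gave 0.396 (one-sided p of the random sets 0.0574, before adjustment). The 2 members were eIF1A and pAbp, the poly(A)-binding protein, which is also the 1 member of the list of RNA-binding and decay proteins in both. The levels of pAbp in the authors' deposited tables were 1.28% and 1.02% in condition 2 with none in condition 1. Those of eIF1A were 4.35% and 3.60%. The ribosomal proteins RpS23 and RpS29 were in both lists (adjusted p = 1), at 0.604% and 0.865% for RpS23 and 3% and 1.49% for RpS29. In condition 1 RpS23 was at 0.0871% and 0.135%, and RpS29 at 0.647% and 0.434%. RpL23A was in the list of replicate 1, at 0.563% and 0.416% in condition 2 of the first and second table, against 0.132% and 0% in condition 1. The stress and immune list had PGRP-SC1a, a peptidoglycan recognition protein, in both, and Hsc70-3, Dredd and GstE1 in replicate 2. Known neuronal ADAR substrates had 2 members in replicate 1, Atpalpha and Adar (Fisher's exact test, adjusted p = 0.377). The translation factor Rack1 was in the list of replicate 1. It was at 0.930% and 0.350% in condition 2 of the first and second table, against 0.213% and 0.0684% in condition 1.

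Members of the signalling and cell type lists were also named, and no difference between the replicates was tested for them. Raf of the EGFR-Ras pathway was in the list of replicate 1, at 34.9% of 43 reads in condition 2 of the first table and 9.09% and 17.02% in condition 1. In the list of replicate 2 were babo and Dad of BMP signalling, Dsor1 of the EGFR-Ras pathway, dome of JAK-STAT signalling, jub of Wnt and Hippo signalling and raptor of insulin-TOR signalling, whose position lies also in Mipp2. Intestinal progenitor genes peb and da, the respiratory gene ND-B14, the vacuolar ATPase gene VhaAC39-1 and the muscle genes up and Zasp66 were further members. Cytoskeleton and junction genes were l(2)gl and dia in replicate 1 and Fak, par-6 and beta-Spec in replicate 2. RNA-binding members in replicate 2 were Imp, tral and gw, and no position was recovered for tral or gw. Many of these were on the X chromosome with a like set of levels in the authors' deposited tables. Hsc70-3 had 0% and 2.94% in condition 1, 0% of 914 reads in condition 2 of the first table and 12.7% of 1013 reads in the second. VhaAC39-1 had 0% and 4.44%, then 0% and 16.4%. beta-Spec had 0% and 4.76%, then 0% and 18.6%. Of the 296 X-chromosome positions of replicate 2, 228 were also in the first table. Of these, 196 had no G read in the first condition 1 library or in condition 2 of the first table, and had G reads in the second condition 1 library. As only mismatched positions are listed, a position without G reads in those libraries nearly always has them in the remaining one. What differs is the condition 1 library: with the first and the second exchanged, the count was 0. Positions absent from the first table are left out of both counts. No member of the enterocyte, enteroendocrine, Notch, cell cycle or gonad and fat body lists was in either list. Chance would give 0.613 and 1.57 enterocyte genes in replicates 1 and 2, and at most 0.732 for each of the others. Random gene sets matched for covered positions gave 1.37 and 2.29 enterocyte genes, and at most 0.832 for each of the others. Only enrichment was tested, not depletion. The absence therefore shows no specificity.

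**Figure D3:**
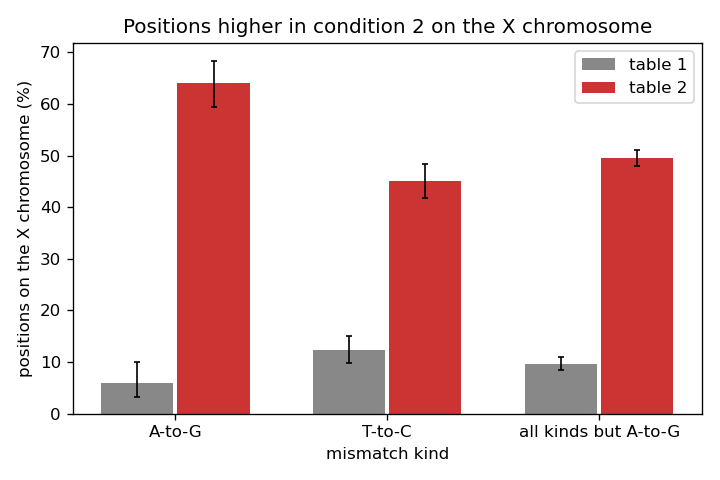
Share in percent (vertical axis) of positions higher in condition 2 that lay on the X chromosome, by mismatch kind (horizontal axis), in the first table (grey) and the second (red). Bars are shares and lines 95% Clopper-Pearson intervals. A position counts under each kind that rose. A-to-G stood at 6.02% and 64.0%, and all kinds but A-to-G at 9.61% and 49.5%.

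Listed positions lay mainly in coding sequence, 61.6% in replicate 1 and 70.4% in replicate 2, and in 3′ UTRs, 29.7% and 23.1%. The comparison was with the other covered A positions of the same genes that carried a mismatch. These were coding in 68.3% and 66.6% and in 3′ UTRs in 24.7% and 25.7%. Covered adenosines without a mismatch are left out, so the shares do not show where editing falls along covered transcripts. Listed positions also had a lower read minimum than the covered ones. No region differed after adjustment. Introns held 3 of 138 positions in replicate 1 (2.17%, against 0.345%), with a two-sided Fisher's exact test p of 0.0154 and an adjusted p of 0.154.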

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

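The minimums of edited reads, the settings without the X chromosome and the handling of the prior in the block were chosen after seeing the data. Sequence context, with its alternatives, was not run. Recovered positions fell from 138 and 432 to 59 and 156 at 20% or more editing and to 88 and 255 at 50 reads, and those of replicate 2 to 136 without the X chromosome. These follow from fewer positions kept. The overlap of the lists kept its direction and stayed past the threshold in every alternative run, with odds ratios from 10.7 at 50 reads to 40.2 without the X chromosome. The comparison of levels depends on the minimum of edited reads. It called 69 higher and 134 lower positions at 1 read, 11 and 31 at 3 reads, and 0 at 2, 5 and 10 reads, and simulated libraries with no difference gave false calls at 1 and 3 reads. The replicate block, taken from the library number of condition 1 and the table number, called 0 higher and 1 lower, with the prior degrees of freedom of limma's moderation held at those without the block. Not held, it called 23 and 60, but also a mean of 22.3 false calls in simulated libraries with no difference, against 0.333 held. The held form was chosen on simulated libraries after the calls of the other had been seen. No column ties these numbers to samples. The difference between the condition 1 libraries correlated with that between the condition 2 libraries at 0.0917, and at 0.0465 without the X chromosome. On the X chromosome, 196 positions of replicate 2 had G reads in the second condition 1 library and none in the first, or in condition 2 of the first table. With the condition 1 libraries exchanged the count was 0. The numbers are thus not shown to pair the libraries, nor is a pairing excluded. Fisher's exact test in each table called 38 higher and 95 lower. Leaving out each of the 4 libraries gave 0 to 0 calls, with the lone library assumed to vary like the others. At an unadjusted p under 0.05, by contrast, these fits gave from 42 to 153 higher and from 25 to 259 lower, so the direction of that balance is not stable. At mismatches over 10%, the A-to-G share moved to 13.53% and 13.51% in condition 1 and to 13.48% and 13.57% in condition 2. The gene list and region tests stayed at 0 past the threshold in the alternatives run. Depth limits single positions: the dve position, with 14 reads, has an interval from 8.39 to 58.1%.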

Other observations

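The tests of editing as the source of most positions, of a rise of all mismatch kinds and of the X chromosome, and the use of listed positions alone and of T-to-C positions in listed genes, were chosen after the result was seen. The excess of X-chromosome positions was not limited to A-to-G. Counts of the other kinds take a position once for each kind that rose, unless stated. Among all kinds but A-to-G, 49.5% of the positions higher in condition 2 lay on the X chromosome in the second table and 9.61% in the first (odds ratio 9.24, two-sided Fisher's exact test p = 1.59e-252).

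The longer list of replicate 2 was weighed first. At positions with reads within 20% in the condition 2 libraries, the ratio of A-to-G positions in the second table to those in the first was 1.76 (95% interval 1.44 to 2.17). This lies above 1 but does not exclude the bound of 1.5 set beforehand. Without the X chromosome the ratio was 0.823 (0.666 to 1.01), although deeper reads would raise every chromosome, which argues against them as the whole cause. Over all chromosomes A-to-G rose by 2.15 and other kinds by 1.72 with each position taken once, or 1.64 with each kind counted. Without the X chromosome the other kinds did not rise either (ratio 0.915, 0.860 to 0.974), which argues against a rise of all kinds across the genome. There A-to-G did not differ from them past the threshold (odds ratio 0.899, two-sided Fisher's exact test p = 0.355). On the X chromosome A-to-G went from 13 to 297 positions and the other kinds from 225 to 1902 (odds ratio 2.70, Fisher's exact p = 0.000196). Neighbouring positions are not independent, so that p is too small, and why A-to-G rose more there was not tested. A candidate explanation is that the flies of that library carried X-chromosome sequence variants that were rarer in the others, a hypothesis found and tested on the same data.

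The second pattern is the listed A-to-G positions themselves. Of all A-to-G positions higher in condition 2 and past the statistic of the lists, 46.8% in the first table and 51.1% in the second had a position of a kind other than A-to-G and T-to-C, also higher, within 200 bases. The same neighbours were found for 37.3% and 41.7% of T-to-C positions. For the recovered positions of the lists alone the shares were 52.2% and 51.9%, against 65.5% and 58.3% of T-to-C positions in the same genes. The wider set was the comparison set beforehand, with such neighbours predicted about as often as for T-to-C if variants were the source. The shares lie above T-to-C there, so that prediction was not contradicted. In listed genes they lie below it, with overlapping intervals (43.5 to 60.7% against 51.4 to 77.8%, and 47.0 to 56.7% against 52.2 to 64.2%). Sequence variants carried together are thus neither excluded nor singled out. Editing by the fusion as the source of most positions is not settled by the odds ratios in either table. In the second, 296 of 432 recovered positions lay on the X chromosome, and 228 of these were also in the first table. Of the 228, 207 had no G read in the other condition 2 library. This argues against editing common to both condition 2 libraries as the source of these 207. A-to-G rose more than other kinds on the X chromosome, so editing in 1 library alone stays open. The odds ratio against T-to-C was 0.635 in the first and 1.10 in the second, but both conditions express ADARcd, so lower positions may be edits as well. With positions called by Fisher's exact test in each table the odds ratios were 0.869 (0.631 to 1.19, p = 0.389) and 1.11 (0.822 to 1.51, p = 0.499). With the conditions exchanged the first ratios would be 1.58 and 0.909, and the listed positions would be lower in the fusion.

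The third pattern is the overlap of the lists. The data gave 37 A-to-G positions in both tables and draws from unchanged libraries a mean of 37.6, but the draws called more positions in the first table. Of the positions called there, 33.6% were also called in the second in the data, against a mean of 20.6% in the draws (range 14.6 to 26.7%). How far the shared condition 1 libraries account for the overlap stays open. Of A-to-G positions called in the first table, 33.6% were called in the second, against 34.1% of T-to-C positions. The odds ratio of 0.980 (95% interval 0.572 to 1.67, Fisher's exact p = 1) leaves a replicated signal specific to A-to-G open. A true overlap of targets at fewer positions stays open.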
